A study of Mus musculus with 2 samples.

How the data were processed

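Polyadenylated RNA from mouse hippocampus was measured in 1 group of 2 libraries, labelled biological replicates 1 and 2. Per the labels, 20 ng of RNA was used, and the fragmentation method was Nextera tagmentation. The files used the mm10 assembly and the M21 gene annotation, per the text deposited beside the tables. The names and versions of the quantification programs are not given in the sources used here. Per the file headers, the first program gave gene and transcript tables in the column layout of RSEM, and the second gave transcript tables in the column layout of kallisto.

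The deposited gene tables hold, per the file headers, the expected count of reads per gene, which need not be whole, the TPM and the FPKM, both scaled for transcript length and depth. The deposited transcript tables hold the same expected count and TPM per transcript, or for the second program the estimated count and TPM. The posterior SD column of the gene tables was not used here. The expected counts summed to 38921671 in replicate 1 and 39499357 in replicate 2, and the estimated counts of the second program to 55151500 and 55608190. The gene tables also hold 26248 rows named by a number only and 96 spike-in rows. These held 9 reads in replicate 1 and 6 in replicate 2, or 2.31e-05% and 1.52e-05% of the total, and stayed out of library sizes and tests.

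Rows were joined to the M21 annotation by gene and transcript identifier, and all 55536 gene rows matched. Coordinates are 1-based on mm10. In 115 cases a symbol has 2 or more gene records, and the record with more reads was used in the gene lists. The second program's values were summed per gene, and genes with no transcript in its tables were set to 0 there. Expected counts were rounded to whole numbers before count tests. Library sizes were scaled by the TMM method of edgeR 4.0.16 in R 4.3.3, which gave factors of 1.005 and 0.995. The biological coefficient of variation came from estimateDisp of edgeR with an intercept only, after filterByExpr. The other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

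Genes were compared between the libraries by a two-sided exact conditional binomial test against the scaled library sizes, over genes with a mean expected count of at least 50, with Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1. This covers counting error only, so it compares the libraries and says nothing about conditions. Log2 ratios used a prior count of 0.5. The median log2 ratio of each gene list, over members with a mean count of at least 10, was set beside 10000 random lists of the same size drawn from 20 bins of mean expression, as a description with no p-value. With 1 group and 2 libraries, outliers and other splits of the samples could not be tested. PCR reads without molecular identifiers are not independent molecules, so the limit for a count of 0, 3 reads per library, covers counting error only.

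Before the data were examined, 38 gene lists were fixed, for cell types, regions, states and receptor families, as was the rule for naming genes. It takes the 25 genes with the highest mean TPM, the 3 highest members and the lowest of each list, all members of the receptor families, the 10 largest and 10 smallest ratios among called genes, and the 10 highest list genes whose dominant transcript differs between programs in both libraries. Some genes that the rule takes are not reported here. Further list members are given as values. Another 4 lists were added after the values of the fixed lists had been seen and before the genes called between the libraries had been viewed, and are reported in the closing part, with 1 count from the second choroid plexus list in the report: a second choroid plexus list of 24 genes, a second interferon list of 26, arachnoid and pial barrier cells with 12, of which 11 matched a record, and motile cilia with 15.

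The steps were tested on simulated data. In libraries simulated with the real means and counting error only, 100 genes were changed by a log2 ratio of 1.5 and 100 by 3. The exact test over 14075 genes recovered 100 and 100, and called 1 of 13875 unchanged genes. The real libraries spread further, with a coefficient of variation of 16.6%. This simulation therefore gives no rate of false calls between them. Coefficients of variation set to 0.05, 0.10 and 0.20 over 16640 genes came back as 0.0505, 0.100 and 0.198. A simulated list of 10 genes shifted by -1 in a pool of 17300 fell at percentile 0 and an unshifted one at 35.6. The alternatives tried were other scalings (relative log expression, library totals), other count and TPM minimums, another pseudocount, FPKM, a preset dispersion of 0.01 in the exactTest function of edgeR, the second program, TPM without mitochondrial genes, leaving out each library, and, chosen after seeing the data, removal of the trend with GC content in 20 bins and calls shared by both programs.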

Results

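Polyadenylated RNA was sequenced from the hippocampus of adult mice aged 6 months, described as C57BL/6 and, more precisely, strain B6NCrl. The hippocampus is the brain region of memory formation that holds the pyramidal neurons of the CA fields and the granule neurons of the dentate gyrus. The series holds 1 group of 2 libraries, labelled as biological replicates with separate tissue samples but 1 shared donor identifier. Each library started from 20 ng of RNA. There is no second condition, so the data describe the levels of genes in this tissue, the spread between the 2 libraries and the difference between 2 quantification programs, and no test between conditions was possible. The test used compares 1 library with the other and covers counting error only, so p-values measure only the difference between these libraries. The labels do not say whether the tissue samples came from separate animals. The gene tables held 38921671 expected reads for replicate 1 and 39499357 for replicate 2. Of 55536 annotated genes, 16720 reached an expected count of at least 10 in both libraries, and 14611 of these were protein-coding.

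The most abundant transcripts were mitochondrial, housekeeping and glial. By mean TPM over the 2 libraries, mt-Rnr2, the large mitochondrial ribosomal RNA, was first, followed by mt-Atp8 and mt-Atp6, which encode subunits of the ATP synthase. Among nuclear genes, the protease inhibitor Cst3 stood at 11871 ± 1716 TPM (SD, n = 2), the ferritin heavy chain Fth1 at 11770 ± 122.3 TPM and the lipid carrier Apoe (chromosome 7, 19696109 to 19699188, mm10) at 7686 ± 37.3 TPM. The 25 highest genes also held mt-Nd1, mt-Co2 and mt-Rnr1, the ribosomal protein genes Rps29, Rpl41 and Rpl38, the respiratory chain genes Cox8a and Cox4i1, Ppia, Actb, Ckb and Ubb. Actb differed between the libraries, with 6836 TPM in replicate 1 and 3183 TPM in replicate 2. Ttr was also among the 25, on the strength of replicate 1 alone, with 14956 TPM there and 117 TPM in replicate 2. CT010467.1, annotated as ribosomal RNA, and the overlapping locus AY036118 on chromosome 17 share sequence, and Gm29216 and Gm28437 on chromosome 1 are annotated as pseudogenes. Gm28437 is uncertain, as it had 4092 TPM in the first program and 4.97 and 1.47 TPM in the second. The 10 highest genes took 14.7% ± 0.567 of all TPM and the 100 highest 37.2% ± 0.302. The 13 mitochondrially encoded protein genes took 6.68% ± 0.09997 of TPM but 2.63% ± 0.121 of expected counts, and 98 genes of cytosolic ribosomal proteins took 10.1% ± 0.372 of TPM but 3.77% ± 0.233 of counts, since TPM divides by transcript length.

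Markers of each hippocampal subfield were present. The CA1 list had a median of 6.35 TPM with 7 of 7 members at 1 TPM or more in both libraries, led by Mpped1 at 104 ± 20.6 TPM, Wfs1 at 69.7 ± 11.5 TPM and Fibcd1 at 31.4 ± 0.969 TPM, with Gpr161 the lowest at 1.04 TPM. The CA2 list had a median of 16.8 TPM with 6 of 7 members at that level. Its highest members were the calmodulin-binding Pcp4 at 456 ± 37.5 TPM, the signalling regulator Rgs14 at 66.3 ± 1.00 TPM and Necab2 at 54.6 ± 9.16 TPM, and Map3k15 was lowest at 0.085 TPM. The CA3 list had a median of 19.3 TPM with 6 of 6 members detected, from Bok at 128 ± 4.47 TPM, Cpne4 at 58.2 ± 3.89 TPM and Socs2 at 28.6 ± 0.516 TPM down to Iyd at 3.42 TPM. The dentate granule list had a median of 12.9 TPM with 7 of 7 members detected, led by the calcium buffer Calb1 at 115 ± 16.3 TPM and C1ql2 at 97.9 ± 0.219 TPM, then Stxbp6 at 16.8 ± 3.51 TPM, with Prox1, the transcription factor of granule neurons, at 12.9 ± 1.70 TPM and Dsp lowest at 1.32 TPM. Genes shared by glutamatergic neurons had a median of 90.9 TPM with 8 of 8 detected. Camk2a, the kinase of excitatory synapses, reached 1545 ± 193 TPM, Cpne6 562 ± 50.1 TPM and Neurod6 94.1 ± 8.03 TPM, and Tbr1 was lowest at 4.01 TPM.

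Inhibitory neurons and glia were also well represented. The list of GABAergic interneurons had a median of 20.5 TPM with 12 of 12 detected. The neuropeptide Npy stood at 319 ± 4.22 TPM, Sst at 134 ± 0.184 TPM, and Lhx6 was lowest at 3.62 TPM. Astrocyte genes had a median of 111 TPM with 10 of 10 detected, led by Aldoc at 1324 ± 47.0 TPM and the glutamate transporters Slc1a3 at 219 ± 28.3 TPM and Slc1a2 at 159 ± 11.5 TPM, with Aldh1l1 lowest at 27.8 TPM. Oligodendrocyte genes had a median of 99.0 TPM with 10 of 10 detected. The myelin genes Mbp at 2288 ± 208 TPM and Cnp at 391 ± 40.8 TPM were among the highest and Ermn at 28.2 TPM was the lowest. Their precursors had a median of 6.16 TPM with 6 of 6 detected, from Pdgfra at 9.91 TPM, Lhfpl3 at 8.77 TPM and Gpr17 at 7.30 TPM to C1ql1 at 1.23 TPM. Microglial genes had a median of 86.7 TPM with 12 of 12 detected, with the complement chains C1qb at 175 ± 4.83 TPM and C1qa at 167 ± 5.76 TPM and Tmem119 lowest at 21.2 TPM.

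**Figure D1:**
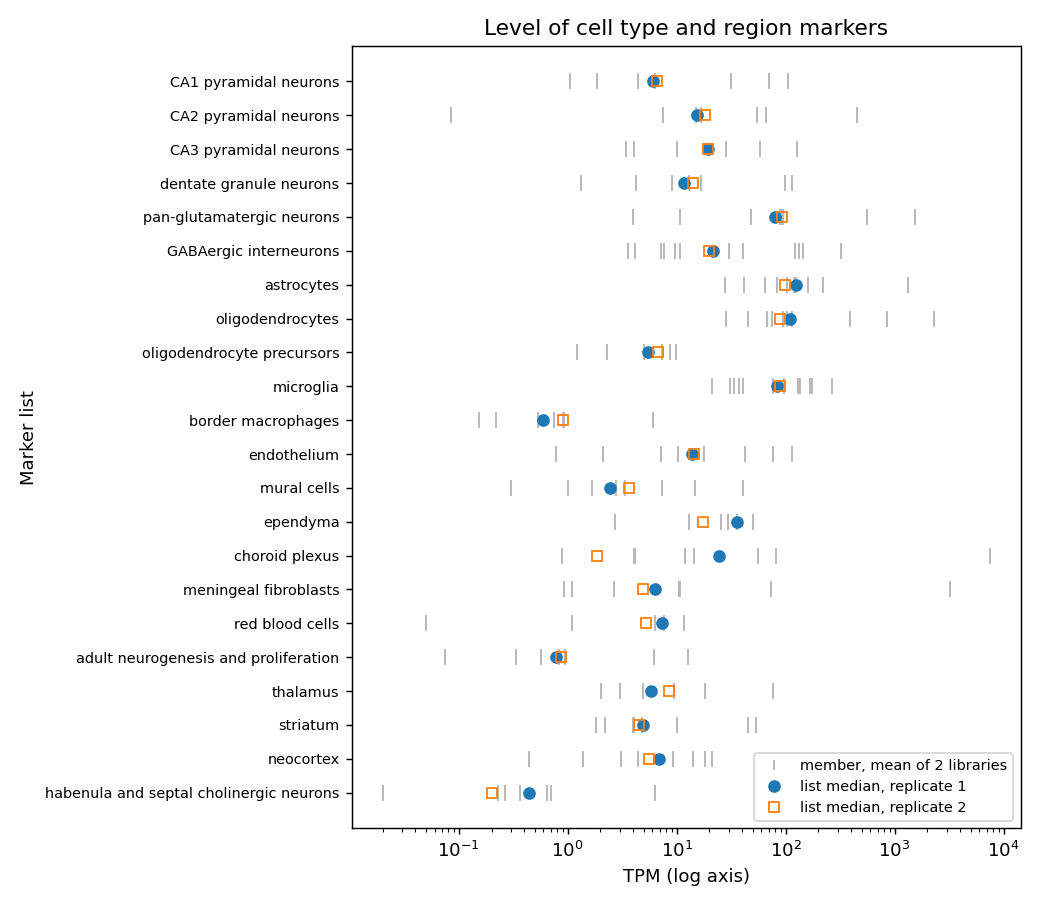
Level of 22 lists of cell type and region markers on a log axis of TPM. Grey ticks are the members (mean of 2 libraries), and the filled circles and open squares are the list medians of replicates 1 and 2, which lie close together for most neuronal and glial lists and far apart for choroid plexus, at 24.7 and 1.88 TPM.

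Genes of vessels, borders and ventricles were measured as lists. The endothelial list had a median of 14.1 TPM with 7 of 8 detected, led by the tight junction gene Cldn5 at 114 ± 24.4 TPM, Itm2a at 77.2 ± 11.5 TPM and Ly6c1 at 42.6 ± 2.38 TPM, with Cdh5 lowest at 0.780 TPM. Mural cells had a median of 3.06 TPM with 6 of 8 detected, led by Vtn at 40.9 TPM, Rgs5 at 14.7 TPM and Acta2 at 7.38 TPM, and Myh11 was lowest at 0.300 TPM. Border macrophages had a median of 0.750 TPM with 1 of 7 detected in both libraries, Pf4 at 6.06 TPM, followed by Cbr2 at 0.935 TPM and Ms4a7 at 0.910 TPM, with Lyve1 lowest at 0.155 TPM. Ependymal genes had a median of 27.5 TPM with 6 of 6 detected, led by Rarres2 at 50.2 ± 8.11 TPM, Mia at 35.5 ± 22.8 TPM and Tmem212 at 29.3 ± 9.14 TPM, with Foxj1 lowest at 2.69 TPM. The median of this list was 35.7 TPM in replicate 1 and 17.6 TPM in replicate 2. Choroid plexus genes had a median of 13.3 TPM with 6 of 8 detected, where the mean hides a wide gap between the libraries: Ttr, the thyroid hormone carrier of cerebrospinal fluid, Kcnj13 at 81.2 ± 110 TPM and Folr1 at 55.7 ± 70.2 TPM were the highest and Aqp1 at 0.895 ± 1.25 TPM the lowest. Meningeal fibroblast genes had a median of 10.4 TPM with 6 of 7 detected, led by the prostaglandin synthase Ptgds at 3231 ± 1873 TPM, Dcn at 74.0 ± 2.63 TPM and Slc6a13 at 10.7 ± 6.07 TPM, with Col1a1 lowest at 0.935 TPM. This median of mean levels lay above that of either library, 6.36 TPM in replicate 1 and 4.94 TPM in replicate 2. Red blood cell genes had a median of 6.34 TPM with 3 of 5 detected, from Hba-a2 at 11.8 TPM, Hbb-bs at 7.62 TPM and Hba-a1 at 6.34 TPM to Alas2 at 0.05 TPM. The near-identical globin copies can exchange reads.

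Markers of neighbouring regions and of new neurons were also measured. The list for adult neurogenesis and proliferation had a median of 0.825 TPM with 2 of 7 detected, Neurod1 at 12.7 TPM and Sox11 at 6.18 TPM, while Igfbpl1 had 0.950 TPM, Dcx 0.825 TPM and the proliferation marker Mki67 0.0750 TPM. Thalamic genes had a median of 7.14 TPM with 6 of 6 detected, from Tcf7l2 at 77.3 ± 26.4 TPM, Prkcd at 18.4 TPM and Ntng1 at 9.40 TPM to Lef1 at 2.02 TPM. Striatal genes had a median of 4.39 TPM with 8 of 8 detected, from Penk at 53.4 ± 2.23 TPM, Ppp1r1b at 45.0 ± 15.3 TPM and Tac1 at 9.98 TPM to Adora2a at 1.81 TPM. Neocortical genes had a median of 6.88 TPM with 7 of 8 detected, from Fezf2 at 21.05 ± 1.83 TPM, Rprm at 18.2 ± 1.81 TPM and Rorb at 14.2 ± 9.74 TPM to Rspo1 at 0.445 TPM. The habenular and septal cholinergic list had a median of 0.365 TPM with 1 of 7 detected, Tac2 at 6.29 TPM, followed by Gpr151 at 0.710 TPM and Chrnb4 at 0.650 TPM, with Pou4f1 lowest at 0.0200 TPM, and its median was 0.44 TPM in replicate 1 and 0.20 TPM in replicate 2. Several members of these lists are also known in hippocampal neurons, so the levels do not measure tissue from those regions.

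Genes that follow activity, stress and the time of day were measured as lists. Immediate-early genes had a median of 19.8 TPM with 12 of 13 detected, led by Junb at 114 ± 1.35 TPM, Egr1 at 42.8 ± 1.54 TPM and Nr4a1 at 35.4 ± 13.5 TPM, with Fosb lowest at 0.560 TPM. Heat shock and stress genes had a median of 27.2 TPM with 6 of 8 detected, led by Hsp90aa1 at 636 ± 37.7 TPM, Hsph1 at 121 ± 0.438 TPM and Ddit3 at 53.4 ± 3.82 TPM, with Atf3 lowest at 0.595 TPM. Glucocorticoid-responsive genes had a median of 22.3 TPM with 7 of 7 detected, from Tsc22d3 at 61.2 ± 11.9 TPM, the mineralocorticoid receptor Nr3c2 at 35.3 ± 0.728 TPM and Sgk1 at 31.5 ± 10.1 TPM to Fkbp5 at 3.65 TPM. Clock genes had a median of 13.2 TPM with 14 of 14 detected, from Nr1d1 at 42.2 ± 5.08 TPM, Dbp at 40.6 ± 1.99 TPM and Per1 at 27.8 ± 5.03 TPM to Per2 at 3.96 TPM.

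Immune and amyloid-related genes covered a wide range. Interferon response genes had a median of 4.69 TPM with 9 of 10 detected, led by Ifit3 at 24.995 ± 14.2 TPM and Ifi27l2a at 23.1 ± 9.09 TPM, with Isg15 lowest at 0.940 TPM, and the list median was 6.49 TPM in replicate 1 and 3.07 TPM in replicate 2. Complement genes had a median of 4.10 TPM with 11 of 14 detected. The 3 C1q chains were the highest, C1qc at 129 ± 2.78 TPM, whereas C3 had 0.705 TPM and Cfb, the lowest, 0.515 TPM. Genes of disease-associated microglia had a median of 3.13 TPM with 7 of 10 detected. Cd9 at 142 ± 16.03 TPM, Lpl at 15.3 TPM and Axl at 14.2 TPM are also made by other brain cells, and Cst7 had 0.7 TPM, Clec7a 0.350 TPM and Itgax, the lowest, 0.145 TPM. The list for amyloid, tau and lipid handling had a median of 28.9 TPM with 12 of 12 detected, led by Apoe, Clu at 427 ± 5.71 TPM and App at 376 ± 31.4 TPM. Mapt, which encodes tau, had 171 ± 31.6 TPM and Abca7 was lowest at 1.16 TPM.

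Glutamate receptor families were each dominated by a few subunits. Gria2 (chromosome 3, 80681450 to 80802835, mm10) made up 63.8% ± 0.351 (SD, n = 2) of the TPM of the 4 AMPA receptor genes, followed by Gria1 at 23.1% ± 1.46, Gria3 at 9.91% ± 0.450 and Gria4 at 3.23% ± 0.663 of TPM or 2.12% of counts, and the family had a median of 47.9 TPM with 4 of 4 detected. Among 7 NMDA receptor genes, with a median of 5.85 TPM and 5 detected, Grin2b (chromosome 6, 135713233 to 136173511, mm10) took 60.4% ± 0.383 of TPM, Grin1 27.4% ± 0.547, Grin2a 9.12% ± 0.383, Grin3a 1.82% ± 0.402, Grin2c 1.02% ± 0.158, Grin2d 0.177% and Grin3b 0.0209%. This order depends on the measure: of expected counts, Grin2b took 32.1%, Grin1 32.8%, Grin2a 29.5%, Grin3a 3.95% and Grin2d 0.269%. Kainate receptor genes had a median of 5.11 TPM with 5 of 5 detected, and Grik2 took 40.8% ± 0.922, Grik4 31.3% ± 2.67, Grik5 15.9% ± 2.04, Grik1 6.82% ± 0.235 and Grik3 5.19% ± 1.32 of TPM. Of counts, Grik3 took 12.4%, more than Grik1 at 6.16%, so the order of these depends on the measure. Metabotropic receptor genes had a median of 12.98 TPM with 7 of 8 detected. Grm5 took 47.8% ± 0.549, Grm3 18.5% ± 1.90 and Grm2 14.996% ± 2.69. Grm6 had 0 reads in both libraries, below 3 reads per library or 0.0771 and 0.0760 CPM. GABA-A receptor genes had a median of 20.0 TPM with 12 of 15 detected. Gabra5 took 17.2% ± 1.03, Gabrb1 11.6% ± 1.24, Gabra4 9.33% ± 0.498 and Gabrd 3.95% ± 0.150, and Gabrq, Gabre and Gabra6 were each below 0.04% of TPM.

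**Figure D2:**
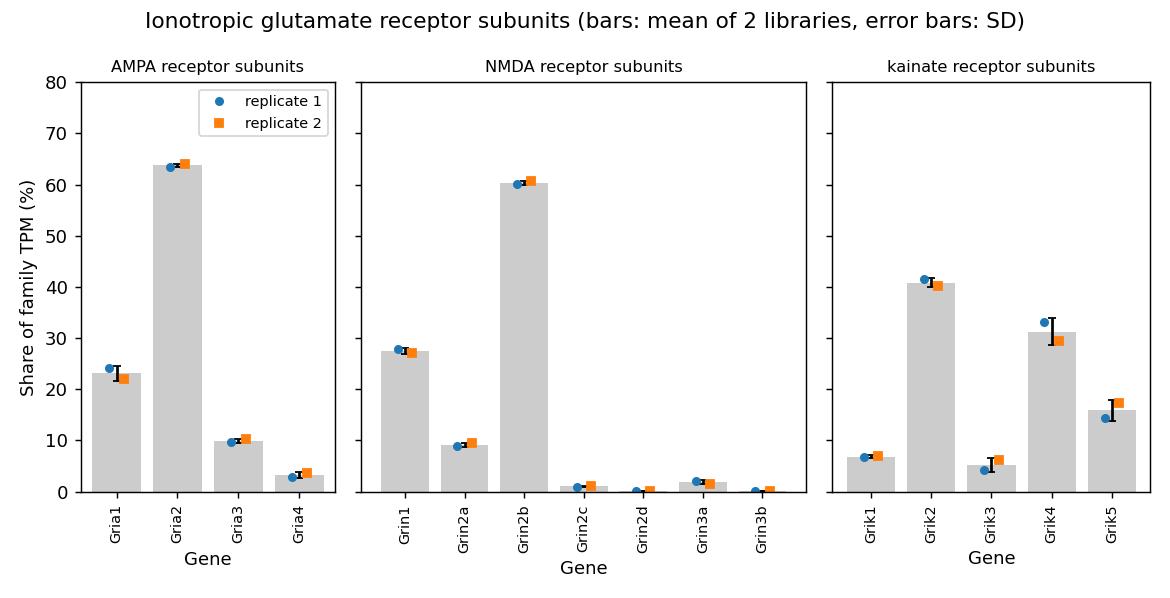
Share of the summed TPM of the AMPA, NMDA and kainate receptor families, in percent, for every subunit gene. Bars are the mean of 2 libraries, error bars the SD, and points the libraries. Gria2, Grin2b and Grik2 are the highest bars of their families, at 63.8%, 60.4% and 40.8%. Of expected counts, Grin2b took 32.1% and Grin1 32.8%.

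Mitochondrially encoded protein genes had a median of 1974 TPM, from mt-Atp8 at 22966 ± 1295 TPM, mt-Atp6 at 16296 TPM and mt-Nd1 at 8748 ± 781 TPM to mt-Nd4l at 24.2 TPM. The second program gave mt-Nd4l 1272 and 974.7 TPM and mt-Co3 5494 and 5150 TPM, against 1431 and 1895 TPM for mt-Co3 in the first. The libraries labelled male held almost no reads of Y-linked genes: Ddx3y, Eif2s3y and Uty had 0 expected reads in both libraries, and Kdm5d had 1 read in replicate 1 and 0 in replicate 2. Their X-linked partners Ddx3x, Eif2s3x, Kdm5c and Kdm6a together had 9916 and 9436 reads. Xist (chromosome X, 103460366 to 103483254, mm10), the RNA that coats the inactive X chromosome, had 694 and 611 reads, or 1.22 ± 0.156 TPM, and its antisense partner Tsix had 358 and 387. The sources used here do not say that strand was used, so reads of this overlapping pair cannot be separated. Nuclear long noncoding RNAs had a median of 6.88 TPM with 4 of 7 detected, from Malat1 at 810 ± 107 TPM, Rian at 215 ± 9.47 TPM and Snhg11 at 13.9 TPM to Miat at 0.420 TPM.

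Transcript tables from both programs were compared for 8477 genes with at least 5 TPM in both libraries and 2 or more annotated transcripts. The same transcript was dominant in the 2 libraries for 92.2% of genes in the first program and 91.7% in the second. Within a library, both programs chose the same transcript for 90.9% of genes in replicate 1 and 89.3% in replicate 2. In 443 genes the programs differed in both libraries. Of 182 list genes compared, 13 were among these, and Ptgds, Cpne6, Bin1, Tyrobp, Nptxr, Gria1, Cpne4, Penk and Slco1a4 were among the highest of them. For Tyrobp, the first program gave 63.1% ± 0.423 of TPM to the transcript for 114 amino acids, and the second gave 96.3% ± 2.20 to that for 140. For Gria1, both leading transcripts encode 907 amino acids and took 60.2% ± 2.90 in the first program for Gria1-202 and 55.5% ± 0.282 in the second for Gria1-201. The App gene (chromosome 16, 84949685 to 85173766, mm10) was dominated by the 695 amino acid form, the main neuronal one. It took 94.3% ± 1.62 (SD, n = 2) of the TPM of complete coding transcripts in the first program and 92.6% ± 1.67 in the second. The 770 amino acid form, which has a Kunitz protease inhibitor domain, took 1.20% ± 0.212 and 0.977% ± 0.0854. The 751 amino acid form had 0% in the first program and 3.82% ± 1.05 in the second, while the 733 form had 3.25% ± 0.882 and 0.0260%, and the 752 form had 1.23% ± 0.952 and 2.59% ± 0.683, so the split of the minor forms depended on the program. The 582 form had 0% in both.

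Across 14845 genes with at least 1 TPM in either library, log2(TPM + 1) had a Pearson r of 0.979 and a Spearman rho of 0.975 between them; genes are not independent replicates, so no p-value was attached. The common biological coefficient of variation, estimated with edgeR over 16640 genes, was 16.6%. Of 14078 genes tested, 97.6% differed by less than 1 on the log2 scale, while 6595 had an adjusted p under 0.05 in the exact binomial test at any size of difference. Every tested gene that differed by 1 or more was among these, so the size of the ratio alone set the calls below.

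Of the lists measured, choroid plexus genes had the largest median difference between the libraries. With a second list of such genes, chosen after the values of the first had been seen, they made up 31 of the 279 genes called higher in replicate 1. Of 8 listed, 8 were higher in replicate 1, 8 passed the exact test, and 8 when adjusted over the list alone. As the ratio alone set the calls, the p-value adds nothing to these counts. Ttr (chromosome 18, 20665280 to 20674321, mm10) had 471673 expected reads in replicate 1, 1.21% of that library, and 3782 in replicate 2, a ratio of 125-fold. The potassium channel gene Kcnj13 was 42.4-fold and the folate receptor gene Folr1 21.6-fold higher in replicate 1. In the list, the median log2 ratio, replicate 2 minus replicate 1, was -4.15, below all 10000 random lists of matched expression. Interferon response genes were also lower in replicate 2, with 10 of 10 members below 0, a median of -0.91 below all random lists, and 3 members past the test. These were Bst2, 2.91-fold higher in replicate 1, Ifit3, 2.30-fold, and Ifit1, 2.05-fold, whose log2 ratio was -0.99 with the trend with GC content removed, short of the threshold of 1. Ependymal genes had a median of -0.54 at percentile 0.06 with 6 of 6 below 0. Of these, Mia was 2.54-fold and Dynlrb2 2.17-fold higher in replicate 1. In the opposite direction, meningeal fibroblast genes had a median of 0.33 at percentile 99.8. Ptgds was 2.43-fold and Slc6a13 2.45-fold higher in replicate 2, but Igf2 was 3.11-fold higher in replicate 1, and the median TPM of this list was lower in replicate 2, at 4.94 against 6.36 TPM.

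The exact conditional binomial test, which compares these 2 libraries and no conditions, called 340 of 14078 genes at a Benjamini-Hochberg adjusted p under 0.05 and a log2 ratio of at least 1 in size. Of these, 279 were higher in replicate 1 and 61 in replicate 2. No tested gene with a ratio of that size was removed by its p-value. With a minimum mean count of 10 in place of 50 the count was 718, and with 200 it was 152. With both programs, 274 were called in the same direction. The 10 smallest ratios belonged to Kcne2, Ttr, Aqp1, Tmem72, Rrh, 2900040C04Rik, Gm10359, Gm28438, Gm45837 and Gm13304. Kcne2 had 1019 reads in replicate 1 and 1 in replicate 2, and Rrh had 140 and 0. The 10 largest belonged to Gm6565, Gm26718, AC121821.3, Npcd, Wdfy1, Crabp2, Prg4, Prss50, Ptger3 and 2210418O10Rik. Crabp2, a retinoic acid binding protein, was 4.07-fold, Wdfy1 4.22-fold and Npcd 11.2-fold higher in replicate 2. Gm10359, Gm28438, Gm6565 and Gm26718 are uncertain: the second program gave Gm10359 the opposite direction, Gm28438 and Gm26718 0 TPM in both libraries and Gm6565 0.230 and 0.317 TPM. For 2210418O10Rik, the ratio of its estimated counts had a log2 of -0.03.

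Of 37 lists with enough reads, 14 had a median outside the central 95% of matched random lists. For lists of unrelated genes 1.9 would fall there, but members of these lists can vary together and some lists share genes. The 1.9 is therefore no measure of chance for these lists. Besides those above, the lists lower in replicate 2 were habenular and septal cholinergic genes (-0.79, percentile 0.67), red blood cell genes (-0.75, percentile 1.32), immediate-early genes (-0.27, percentile 0.04), complement (-0.21, percentile 1.52), astrocytes (-0.20, percentile 0.20) and mitochondrially encoded proteins (-0.20, percentile 0.095). Higher in replicate 2 were border macrophages (0.54, percentile 98.7), mural cells (0.35, percentile 99.8), glutamatergic neurons (0.22, percentile 99.6) and CA2 neurons (0.20, percentile 98.0), whose mean of -0.19 had the opposite sign, with Map3k15 at -2.49. Of these, 4 lists fell inside the central 95% under some alternatives: complement with log2(TPM + 1), the second program and the GC trend removed (percentiles 12.65, 8.75 and 5.41), CA2 neurons with log2(TPM + 1) and the GC trend removed (96.9 and 93.9), border macrophages with the second program (96.3), and the habenular and septal list with log2(TPM + 1) (3.47). Medians that shrank but stayed outside it under the alternative named were those of mitochondrially encoded proteins, at -0.107 with the GC trend removed, and of immediate-early genes, at -0.148, and border macrophages, at 0.227, with log2(TPM + 1). The border macrophage median is the ratio of Cbr2, which had only 19 reads in replicate 1 and 28 in replicate 2. In that list 3 of 7 members had enough reads for the test, and 0 were called. The astrocyte list had a mean of -0.07 and 3 of 10 members above 0. Other lists lower in replicate 2 were also split. Members above 0 were 5 of 13 for immediate-early genes, 5 of 14 for complement and 4 of 13 for mitochondrially encoded proteins. In the habenular and septal list they were 2 of 6, and its summed TPM was 8.40 in replicate 1 and 8.65 in replicate 2. The 13 mitochondrially encoded protein genes together took 6.75% of TPM in replicate 1 and 6.60% in replicate 2. All 37 mitochondrially encoded genes took 10.2% in replicate 1 and 10.7% in replicate 2, so the list does not stand for mitochondrial RNA as a whole. Single members past the test were Egr2 and Chrnb4, Rorb, Cd59a and mt-Nd4l, higher in replicate 1, and the complement gene C2, higher in replicate 2. The call of mt-Nd4l rests on the first program, since the second gave a log2 ratio of -0.27. On the TPM scale, Egr2 stood at 2.22 and 1.93 TPM and C2 at 1.04 and 1.61 TPM, each less than a log2 difference of 1. The remaining 23 lists had medians from -0.13 to 0.18. Over the 38 lists, 22 of 289 tested places were past the test, and 22 adjusted over the list alone. That match adds no support, since the ratio alone set the calls.

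**Figure D3:**
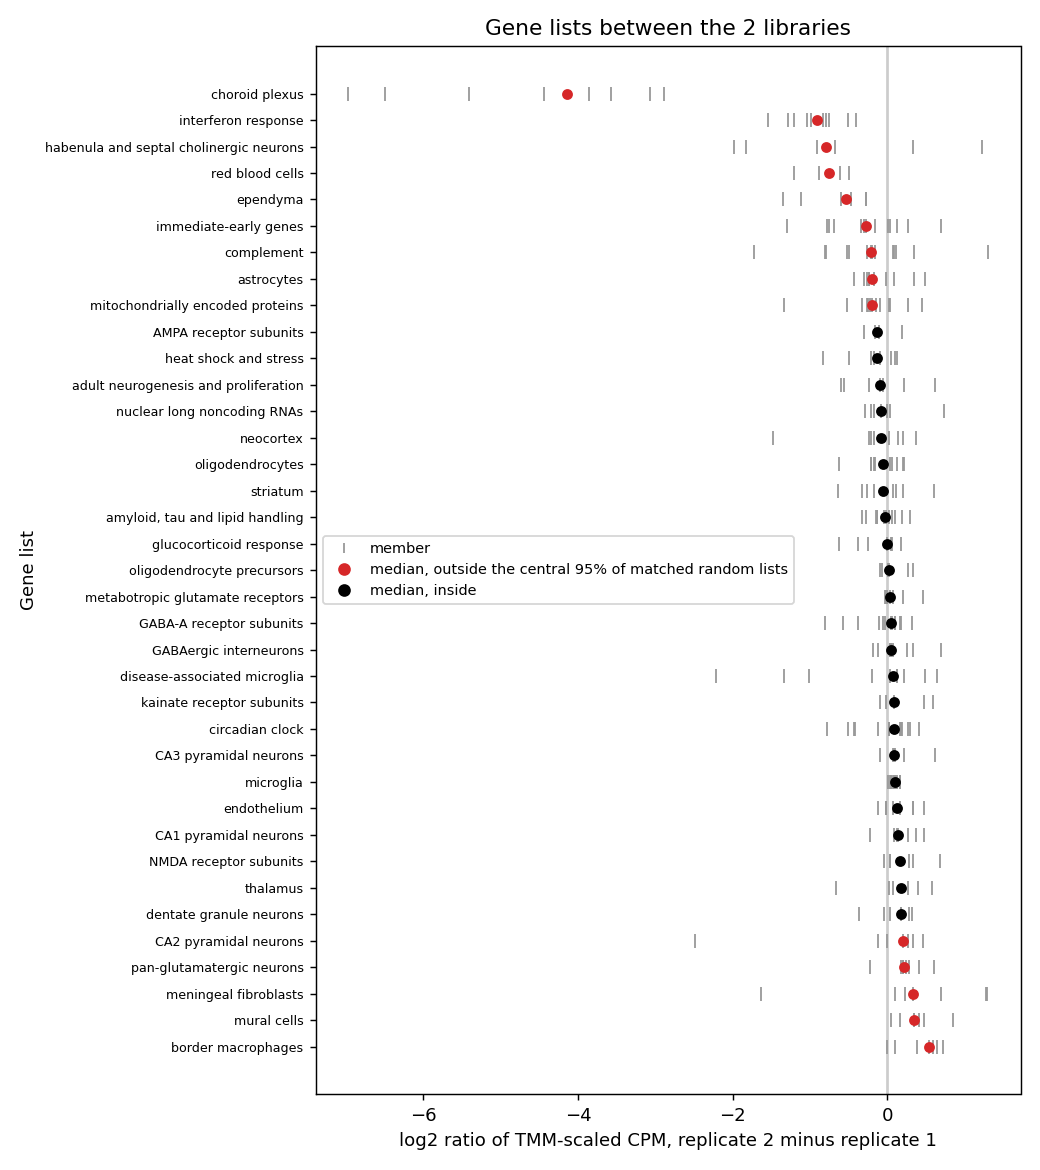
log2 ratio of scaled counts, replicate 2 minus replicate 1, for 37 gene lists. Grey ticks are members with a mean count of at least 10, and circles are list medians, red where outside the central 95% of matched random lists; choroid plexus lies at -4.15 and border macrophages at 0.54.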

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

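Among the tests below, that of the second interferon list was set before its result was seen, and the others were chosen after the values had been seen. With 1 group in the design, no difference between groups was available as a biological explanation to test, and the tests of cells and tissues below concern the make-up of the samples.

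Signal outside the main measurement was looked at in 2 places, and in 1 of them a row was above the limit of 3 reads that a count of 0 allows. In the second program, the spike-in row ERCC-00099 held 142 estimated reads in replicate 1 and 105 in replicate 2, while the first program gave 0 reads to all 96 spike-in rows. The 26248 rows named by a number only held 9 expected reads in replicate 1 and 6 in replicate 2 in all. The limit is for a single row, so it cannot be set against these sums.

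Choroid plexus genes were far higher in replicate 1, with Ttr at 14956 and 117 TPM. The second program gave a median log2 ratio of -4.10 for the list and removal of the trend with GC content left it at -4.11, which argues against misassignment by the first program and against that trend as the whole cause. A second list of 24 choroid plexus genes had a median of -3.49, with 23 of 24 higher in replicate 1 and 23 past the test, with Enpp2 at 823 and 96.5 TPM and Cox8b at 101 and 2.05 TPM, and 13 of its genes reached 1 TPM in both libraries. A candidate explanation is a piece of choroid plexus in the tissue taken for replicate 1. It stays a hypothesis, since 2 libraries do not show how the tissue was cut.

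The libraries labelled male held at most 1 expected read on the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and at least 611 on Xist. The second program gave the 4 genes 26.8 and 23.0 estimated reads, at most 0.197% of the reads of their X-linked partners. It has Y-linked rows with reads of its own, so this argues against a Y chromosome missing from the alignment reference as the cause. Female tissue under a male label is a candidate explanation, and the labels themselves give the sex as not collected in 1 field and male in another. Xist stood at 1.22 TPM and overlaps Tsix, and there is no library of known sex here to set that level against.

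Interferon response genes were higher in replicate 1, with a median log2 ratio of -0.91 between replicate 2 and replicate 1. The choice of the list does not account for it, since a second list of 26 genes with no shared member had a median of -0.53 at percentile 0, with 25 of 25 measured members higher in replicate 1 and 2 past the test. Microglial and endothelial genes did not go the same way, and the lower of their 2 medians was 0.10, which argues against a larger share of these cells in replicate 1. Removal of the GC trend left the list at percentile 0 with a median of -0.88. Whether the choroid plexus tissue may carry part of the -0.91 cannot be told apart from a change in the rest of the tissue, because no choroid plexus profile was set beside it.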

How the results depend on the processing

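The GC correction and the calls shared by both programs were chosen after seeing the data. Of the alternative values for the main results, 39 moved, 7 became weaker and none reversed. The other 86 stayed within their spread, on their side of the threshold or, for counts of genes, within a fixed fold range of the main count. That range is wide, and took 22128 genes detected at an expected count of at least 1 as unmoved from 16720. In 4 lists a shift inside the central range fell outside it: dentate granule neurons with log2(TPM + 1) (0.226) and the GC trend removed (0.21), thalamus (0.246) and NMDA receptor genes (0.33) with log2(TPM + 1), and endothelium with the second program (0.191). Where a value moved the cause was not tested, except that counts do not divide by transcript length, that a lower minimum tests more genes, and that a dominance minimum drops close pairs. Pearson r was 0.955 with log2(TPM + 0.1), 0.993 with no filter, 0.969 at 10 TPM or more and 0.981 with FPKM. The coefficient of variation was 18.9% with no filter and 17.6% in the second program. Genes differing between the libraries numbered 718 at a mean count of at least 10 and 152 at 200; the other 6 alternatives gave 274 to 411. The CA2 shift fell inside the central range with log2(TPM + 1) (0.159) and with the GC trend removed (0.144), border macrophages with the second program (0.397), the habenular and septal list with log2(TPM + 1) (-0.257), and complement with log2(TPM + 1) (-0.093), the second program (-0.116) and the GC trend removed (-0.146). The median level over the 38 lists was 12.9 TPM, 11.0 in the second program, and 10.7 to 12.4 with 1 library left out.

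With expected counts in place of TPM, the shares were 61.3% for Gria2, 32.1% for Grin2b, 34.4% for Grik2 and 48.6% for Grm5; the second program gave 69.6% for Grin2b, 42.3% for Grik2 and 49.4% for Grm5. Class shares by counts were 2.63% for mitochondrial proteins, 3.77% for ribosomal proteins, 10.5% and 26.2% for the 10 and 100 highest genes and 91.9% for protein-coding genes. In the second program they were 6.95%, 8.21%, 18.5%, 43.4% and 76.3%. The same dominant transcript in both libraries was found for 89.7% of genes at 1 TPM, 93.8% at 20 TPM and 99.8% where the leading transcript held at least 60% (first program), and for 89.6%, 94.1% and 99.9% (second program). Between programs it was 90.03% and 99.4% in replicate 1 at 1 TPM and with the 60% minimum, and 88.5%, 90.1% and 99.3% in replicate 2 at 1 TPM, 20 TPM and with that minimum. The 695 amino acid App form had 92.6% in the other transcript table. Among single lists, 48 levels moved by more than the spread of the libraries, and the second program's medians were 0.655 to 1.32 times the first's. Depth limits the genes with low counts, which the main test, at a mean count of at least 50, leaves out.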

Other observations

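Other lists, added after the first values had been seen, described the borders and ventricles further. Of 15 genes of motile cilia, 2 of which are also in the ependymal list, 13 were higher in replicate 1, with a median log2 ratio of -0.75, replicate 2 minus replicate 1, at percentile 0, and 3 were past the test, among them Rsph1 at 18.3 and 6.69 TPM and Rsph4a at 2.14 and 0.88 TPM. The list of arachnoid and pial barrier cells had a median of 1.19 at percentile 100 over 10 members, 7 above 0 and 3 below. Of the 10, 4 were past the test and higher in replicate 2, Crabp2, Aldh1a2, Slc22a6 and Fmod, and 1, Slc13a4, was higher in replicate 1, at 14.8 and 5.32 TPM. The summed TPM of the list was 53.03 in replicate 1 and 50.51 in replicate 2.

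Wdfy1 (chromosome 1, 79702262 to 79776143, mm10) had 376 reads in replicate 1 and 1598 in replicate 2. Nnt, named after its values were seen, has 2 gene records that overlap, with 712 and 425 reads for 1 record and 483 and 478 for the other. The 4 neighbouring loci AY036118, Gm26917, Gm42418 and CT010467.1 on chromosome 17 took 1.57% of TPM in replicate 1 and 2.84% in replicate 2. Across 14072 genes, the log2 ratio between the libraries had a Spearman rho of 0.268 with GC content, with medians of -0.09 in the 10% of genes with the lowest GC content and 0.16 in the 10% with the highest.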
